A study of Mus musculus with 6 samples.

How the data were processed

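RNA was extracted with a column kit from NK cells sorted from mouse spleen, and sequencing libraries were made by an Illumina protocol, per the labels' protocols. The sort kept cells positive for NK1.1 and NKp46 and negative for CD3 and for the CD1d tetramer, which removes T cells and NKT cells. There were 6 libraries, 3 from mice given IL-15 cytokine complexes (IL-15C) and 3 from mice given IL-2 cytokine complexes (IL-2C). Groups and replicate numbers came from the sample titles.

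Per the submitters' processing notes, TopHat2 2.0.13 and Cufflinks 2.2.1 were used with the mm10 mouse genome; the gene annotation is not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of transcript, scaled by the number of mapped fragments of the library) with the lower and upper bound of each estimate, 1 table per library, per the file headers. The authors also deposited a table of group FPKM values from Cuffdiff, the comparison program of Cufflinks, with interval bounds and with no fold change or p-value. FPKM is not a count, so no count model was fitted. Both kinds of table are in FPKM but were scaled separately, and no level was compared across them.

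Each library held 24885 rows for 24343 genes. The rows of 280 genes listed more than once were summed, and 10 genes whose estimate had failed in any library were left out. Each deposited interval was read as the estimate plus or minus 2 SD of a Poisson count, which gives an implied fragment number per gene. Of the low rows, with 5 to 200 implied fragments, between 29.4% and 31.3% per library gave a value within 0.02 of a whole number. Genes with several isoforms or shared reads need not do so. The implied total was 23543141 to 27229145 fragments per library. Intervals from these numbers cover counting error only.

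The main test was limma's moderated test with an intensity trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), two-sided. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which left 9831. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low genes. Changes are given as IL-15C minus IL-2C with the standard error (SE) of the fit. No label says whether the libraries came from separate mice, so p-values measure the spread between these samples, which may be technical. The test was run on 10 simulations of the 9831 genes with 200 changed genes. It recovered 40.1% of genes changed by 0.25 on the log2 scale, 92.7% at 0.5 and 100% at 1. Of its calls, 5.08% were false. The simulated values were normal, independent between genes and drawn from limma's fitted spread, without differences between libraries. A false share near the threshold follows from that design, so it does not measure the false share in these data.

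There were 30 gene lists, covering NK cell function, NK stages, library quality and other cell types. The 26 with at least 5 tested members were compared with all other genes by limma's camera test with a preset correlation of 0.01 between genes, adjusted over the 26 lists. An estimated correlation and the fry test, which asks whether a list's genes move on balance one way, were alternatives. The genes named are the 12 with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap and whose higher group mean was at least 5 FPKM, up to 5 members per list with the smallest adjusted p, and a set of genes of interest that includes Il10 and the sort markers. The test, its threshold, the lists and this naming rule were fixed before the data were examined. A gene that this rule would name is not reported here.

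The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, and 3 other scalings, namely a common library median, rescaling each library to one common sum (TPM) and quantile normalization. The others were limma without the trend, array weights, a replicate block, leaving out each library in turn and a 2-fold minimum. The planned overlap with the authors' Cuffdiff calls was not run, because the deposited table used here holds no calls. In its place, and after the data were seen, genes whose deposited group intervals did not overlap were counted. Other alternatives added then were removal of GC content and transcript length trends with median scaling, a covariate for B cell and MHC class II genes, keeping the genes with failed estimates, and leaving out genes at 0 in any library. GC content and length came from the GENCODE annotation of mm10 and covered 99.5% of tested genes.

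Gene positions are those of the authors' files on mm10, written 1-based. After adding 1 to each start, 61.8% of 22916 loci had the same start as the RefSeq annotation of that build, against 3.19% without it. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, exact tests and plots.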

Results

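Gene expression was measured by RNA sequencing in NK cells sorted from the spleens of female C57BL/6 mice given cytokine complexes of either IL-15 (IL-15C) or IL-2 (IL-2C). In such complexes the cytokine is bound to a carrier protein, which prolongs its action; the labels do not name the carrier. Each group had 3 libraries. The deposited intervals implied 23543141, 24553178 and 24580391 fragments in the IL-15C libraries and 23665058, 27040660 and 27229145 in the IL-2C libraries. Between 14491 and 14695 genes per library had an FPKM above 0. Ccl5, a chemokine abundant in NK cells, was the most abundant gene of every library at 10472 to 12176 FPKM. Log values of libraries correlated across genes with Pearson r of 0.991 to 0.994 within IL-15C, 0.996 to 0.997 within IL-2C and 0.990 to 0.995 between groups. The first principal component held 37.8% of the variance and placed all 3 IL-15C libraries on the side opposite to the 3 IL-2C libraries. The second component held 26.5% and had IL-15C replicates 1 and 2 at its opposite ends, at 12.9 and -8.14. IL-15C replicate 2 also lay farthest out on the first component, at -12.8. Untreated cells were not analysed here, so each difference is between the 2 treatments.

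The comparison asks how NK cells of IL-15C-treated mice differ from those of IL-2C-treated mice; the study concerns protection from cerebral malaria by NK cells stimulated with IL-15 complexes. IL-15C cells had more transcripts of Ly6a, a surface protein also called Sca-1, of the protease genes Gzmk and Gzmb, of Ifng, the gene of interferon gamma, and of Bcl2, which blocks apoptosis. They had less of Fcgr2b, an inhibitory receptor for IgG, of the transcription factors Batf3, Zeb2 and Tcf7, and of the trafficking receptors S1pr5, Cx3cr1 and Cxcr4. Ly6a, Gzmk, Fcgr2b and Batf3 kept their call with each library left out in turn. The other genes named so far did not, and Cx3cr1 also lost its call under another scaling. Most differences were small. Of 9831 genes tested by limma, 169 were higher and 464 lower in IL-15C at an adjusted p under 0.05, with median log2 changes of 0.30 and -0.25. The 3 values of one group all lay above those of the other for 33.3% of tested genes, where chance gives 10% on average over splits. Genes share differences between libraries, so a single split can lie far from 10% without an effect of treatment. All 633 called genes were separated in this way, which passing the test with 3 against 3 nearly requires. At least a 2-fold change on the log2(FPKM + 1) scale was reached by 4 of the called genes, Ly6a, AA467197, Gzmk and Lilrb4a, all higher. On that scale, which shrinks the change of low genes, 0 called genes were at least 2-fold lower in limma, although the mean FPKM of Batf3 was 3.58-fold and that of Top1mt 2.05-fold higher in IL-2C; 2006 genes were lower and 637 higher at an unadjusted p under 0.05.

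The split between directions depended on scaling. The median log2 change of all tested genes was -0.04, and 64.7% of them were below 0. Scaling each library to a common median gave 324 higher and 205 lower genes, quantile normalization 307 and 269, and rescaling to TPM 208 and 328. All 169 higher genes remained called after median scaling, as did 205 of the 464 lower ones. The counts also rested on single libraries: without IL-2C replicate 2 they were 14 higher and 15 lower, without IL-2C replicate 1 they were 27 and 19, and without IL-2C replicate 3 they were 85 and 241. Without IL-15C replicate 2 they were 72 and 122, and without IL-15C replicate 3 they were 109 and 153. Leaving out IL-15C replicate 1, which lay at one end of the second component, raised them to 175 and 572. In the authors' deposited table of group values, the log2 changes of the 9831 genes correlated with those of the libraries at r = 0.914 across genes, which are not independent replicates. All 633 called genes had the same sign there, and the median change was -0.000321. The table pools the same groups, and the called genes were all separated between them. A shared sign was therefore nearly fixed in advance and adds no independent support.

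Ly6a showed the largest rise. Its mean was 8.64 FPKM ± 2.18 (SD, n = 3) in IL-15C and 1.84 ± 0.585 in IL-2C, 4.70-fold, with a log2 change of 1.76 ± 0.17 (SE) and a limma adjusted p of 0.00191. The gene lies on chromosome 15 at 74994877 to 74998031 in mm10. AA467197, on chromosome 2 at 122637887 to 122641076, averaged 6.43 FPKM ± 0.543 against 1.41 ± 0.372, a log2 change of 1.63 ± 0.11. Gzmk, which encodes the serine protease granzyme K, averaged 28.9 FPKM ± 2.40 against 13.5 ± 2.31, and rose by 1.06 ± 0.11. Lilrb4a, an inhibitory receptor gene, rose by 1.02 ± 0.20, and its neighbour and near-identical relative Lilr4b by 0.81 ± 0.17; reads shared between the pair make their separate values uncertain. Thy1, the surface protein CD90, rose from 78.8 FPKM ± 5.76 to 138 ± 14.9. S100a4, a calcium-binding protein gene, rose from 121 ± 18.1 to 215 ± 17.2. Spp1, which encodes the secreted protein osteopontin, rose by 0.76 ± 0.09, and Lgals3, which encodes galectin-3, by 0.76 ± 0.13. Plac8, Bspry and Lpar5, a receptor for lysophosphatidic acid, completed the 12 largest rises among genes of at least 5 FPKM, at 0.92, 0.87 and 0.77. All 12 kept their call under each of the 3 other scalings. With each library left out in turn, 8 passed every time, and 8 was also the number without IL-2C replicate 2, against 9 without IL-2C replicate 1 or IL-2C replicate 3; Lilrb4a, Plac8, Lilr4b and Lgals3 were the genes lost in at least 1 omission.

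**Figure D1:**
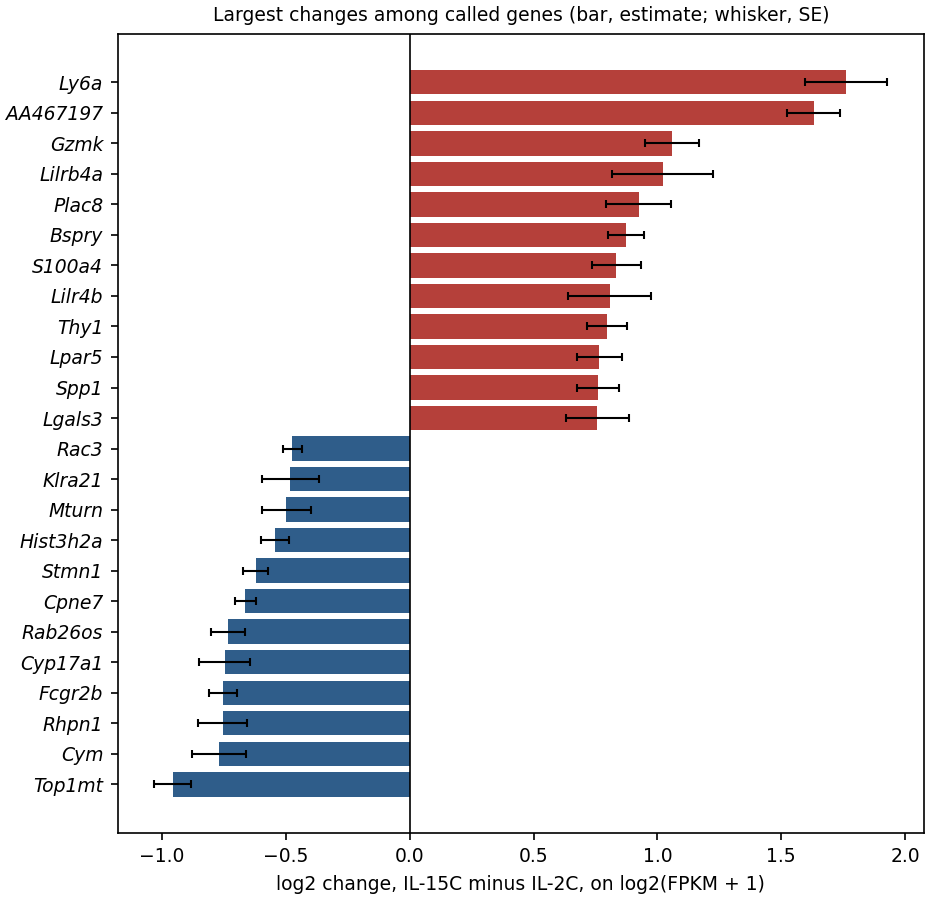
Log2 change between IL-15C and IL-2C (horizontal axis, on the log2(FPKM + 1) scale) of 12 rises and 12 falls, with bars for the estimate and whiskers for its SE. They are the largest among called genes whose groups did not overlap and whose higher group mean was at least 5 FPKM. That limit leaves out Batf3, at -0.93. The rises reach 1.76 for Ly6a, and the falls reach -0.96 for Top1mt.

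Among the falls, Top1mt, which encodes the mitochondrial type I topoisomerase, averaged 9.04 FPKM ± 0.426 in IL-15C and 18.5 ± 2.17 in IL-2C. Its log2 change was -0.96 ± 0.07, with a limma adjusted p of 0.000702. It lies on chromosome 15 at 75657033 to 75678790, next to Rhpn1 at 75704288 to 75714419, whose log2 change was -0.76 ± 0.10. Fcgr2b, on chromosome 1 at 170960559 to 170976071, averaged 27.4 FPKM ± 2.08 in IL-15C against 46.7 ± 1.26, a log2 change of -0.75 ± 0.06. Its implied fragments were 1204, 1352 and 1431 in IL-15C against 1818, 2059 and 2007. That relative gap is smaller than the gap in FPKM, and the cause was not tested. Stmn1, whose product destabilises microtubules, fell by 0.62 ± 0.05, and Rac3, a small GTPase gene, fell by 0.47 ± 0.04. Cpne7 and Mturn changed by -0.66 and -0.50. The protease gene Cym and the steroid-synthesis gene Cyp17a1 changed by -0.77 and -0.75, the antisense transcript Rab26os by -0.73 and the histone gene Hist3h2a by -0.54. Klra21, one of the closely similar Ly49 receptor genes, had -0.48 ± 0.11 and is uncertain for that reason; values of Rab26os can hold reads of the gene on the other strand. Mturn and Klra21 lost their call under another scaling, and the other 10 genes kept it. With each library left out in turn 7 passed every time, 7 passed without IL-2C replicate 2, 8 without IL-2C replicate 1, 10 without IL-2C replicate 3 and 11 without IL-15C replicate 2; Cym, Rhpn1, Cyp17a1, Mturn and Klra21 were the genes lost.

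Il10 was measured near the limit of detection, below the 1 FPKM filter. Its values were 0.817, 0.217 and 0.352 FPKM in IL-15C and 0.151, 0.125 and 0.159 in IL-2C, from 38, 11 and 18 implied fragments against 7, 7 and 9. The means were 0.462 ± 0.315 (SD, n = 3) and 0.145 ± 0.018, a ratio of 3.19, and every IL-15C value lay above every IL-2C value. Without IL-15C replicate 1 the ratio was 1.96. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow, and in the limma fit without a filter the adjusted p was 0.27. The fragment ratio of all IL-15C to all IL-2C libraries was 3.13, with an exact 95% interval of 1.93 to 5.27 that covers counting error only. The gene lies on chromosome 1 at 131019845 to 131024970. Il2ra, the high-affinity IL-2 receptor chain, was also below the filter, at 0.850 ± 0.444 against 0.465 ± 0.091 (exact permutation p = 0.2). The ratio of means of Il2ra was 1.83, and 1.31 without IL-15C replicate 1.

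**Figure D2:**
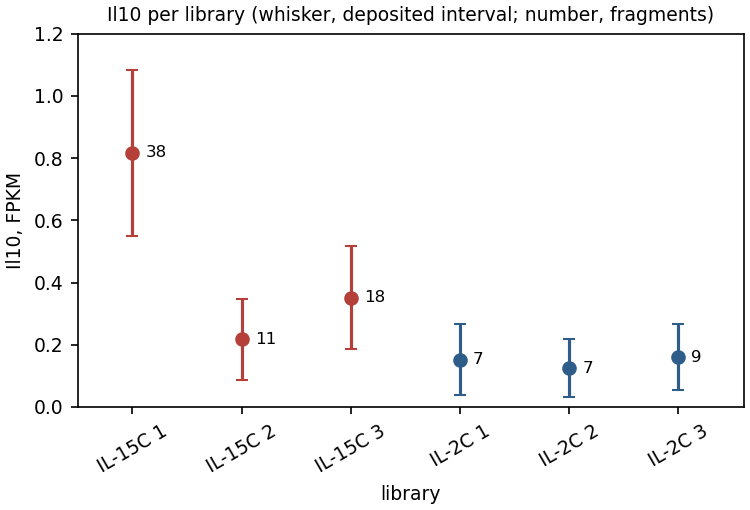
Il10 in each library in FPKM (vertical axis), with whiskers for the deposited interval and numbers for the implied fragments. The IL-15C values run from 0.217 to 0.817 and the IL-2C values from 0.125 to 0.159, and the intervals of IL-15C replicates 2 and 3 overlap those of IL-2C.

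Of 14 tested cytokine genes, 2 rose, 0 fell and 12 did not pass (limma; 3 rose when adjusted over the list alone). Spp1 was one of them, and Ifng rose from 32.0 FPKM ± 2.34 to 41.3 ± 2.66, a log2 change of 0.36 ± 0.06. The chemokine gene Ccl4, the one added over the list alone, had 0.47 ± 0.13 (adjusted p = 0.0653 over all genes), and Tgfb1 had 0.11 ± 0.07. As a group the cytokine genes stood above other genes (camera adjusted p = 0.0202), but the adjusted p was 0.738 with an estimated correlation, 0.144 without IL-15C replicate 1 and 0.0564 without IL-2C replicate 1, and the call also ended after median scaling and quantile normalization. Of 22 granule genes, 2 rose, 0 fell and 20 did not pass, with 3 risen when adjusted over the list alone. These were Gzmk and Gzmb, granzyme B, which rose from 360 FPKM ± 19.0 to 563 ± 67.9, and, over the list alone, Gzmc at 0.52 ± 0.14. Granzyme A and perforin showed no change past the test, with log2 changes of 0.08 ± 0.10 for Gzma and 0.10 ± 0.08 for Prf1. The granule list passed camera with an adjusted p of 1.45e-06, which was 0.738 with an estimated correlation and 0.000607 without IL-15C replicate 1. Its mean was 6.69 in that library, 6.55 and 6.53 in the other IL-15C libraries and 6.49, 6.37 and 6.42 in IL-2C. Spp1 and Gzmk passed with every library left out in turn, while Gzmb and Ifng did not pass without IL-2C replicate 2 and Ifng not without IL-2C replicate 1 either.

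Of 24 genes linked to IL-10 expression in lymphocytes, 3 rose, 0 fell and 21 did not pass, with the same counts of 3 and 0 when adjusted over the list alone. The costimulatory receptor gene Tnfrsf9 (4-1BB) rose by 0.70 ± 0.12, the inhibitory receptor gene Tigit by 0.72 ± 0.12 and the immediate early transcription factor gene Egr1 by 0.59 ± 0.12. Lag3 had 0.51 ± 0.17 (limma adjusted p = 0.0894). Apart from Egr1, the transcription factor genes of the list did not pass. Examples outside the naming rule were Maf at 0.09 ± 0.05, Batf at 0.09 ± 0.06 and Stat3 at 0.03 ± 0.05. Nfil3 had -0.005 ± 0.06, Prdm1 -0.10 ± 0.06 and Irf4 -0.22 ± 0.11. The list's camera adjusted p was 0.000972, which was 0.738 with an estimated correlation and 0.00184 without IL-15C replicate 1. That library had the highest list mean, 3.90 against 3.71 and 3.68 in the other IL-15C libraries and 3.67, 3.66 and 3.60 in IL-2C. Of 27 genes that respond to gamma-chain cytokines and STAT5, 4 rose, 0 fell and 23 did not pass, with 6 risen when adjusted over the list alone. Bcl2 rose from 11.8 FPKM ± 1.59 to 18.8 ± 1.78, a log2 change of 0.63 ± 0.09. The kinase gene Jak3, which signals from the common gamma chain, rose by 0.21 ± 0.04, and Tnfrsf9 and Gzmb belong to this list too. Socs3, a feedback inhibitor of cytokine signalling, had 0.30 ± 0.08 (adjusted p = 0.054). The list's camera adjusted p was 2.83e-07, which was 0.738 with an estimated correlation and 3.71e-06 without IL-15C replicate 1. The mean of this list was 5.24 in that library, 4.95 and 4.94 in the other IL-15C libraries and 4.86, 4.87 and 4.79 in IL-2C. The receptor chains had log2 changes of 0.16 ± 0.08 for Il2rb and 0.15 ± 0.05 for Il15ra, neither past the test. Of the 6 risen genes named here, all passed without IL-15C replicate 1, 5 without IL-15C replicate 2 or IL-15C replicate 3, 3 without IL-2C replicate 3, 2 without IL-2C replicate 1 and 0 without IL-2C replicate 2, the highest limma adjusted p of any omission being 0.1195.

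Of 25 activating receptor genes, 2 rose, 1 fell and 22 did not pass; when adjusted over the list alone, 3 rose and 5 fell. Tnfrsf9 and Cd27, a costimulatory receptor, rose, Cd27 by 0.22 ± 0.05, and Klre1 fell by 0.30 ± 0.06. Klrk1, which encodes NKG2D, had -0.18 ± 0.05 (limma adjusted p = 0.0591). Of 16 inhibitory receptor and checkpoint genes, 3 rose, 1 fell and 12 did not pass; when adjusted over the list alone, 4 rose and 2 fell. Tigit, Lilrb4a and Klra5 rose, the last by 0.34 ± 0.06, and Klra9 fell by 0.23 ± 0.05. The Ly49 genes Klra5 and Klra9 share reads with close relatives and are uncertain. Klrd1, which encodes CD94, had -0.22 ± 0.06 (adjusted p = 0.0512). Neither list passed camera, with adjusted p of 0.532 and 0.0968. Klra9 lost its call under another scaling. Of the 7 called genes named here, 6 passed without IL-15C replicate 1, 4 without IL-15C replicate 2, 3 without IL-15C replicate 3, 2 without IL-2C replicate 3 and 0 without IL-2C replicate 1 or IL-2C replicate 2.

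Genes of both the mature and the immature NK stage moved in both directions. Of 21 mature-stage genes, 1 rose, 4 fell and 16 did not pass; when adjusted over the list alone, 1 rose and 6 fell. Zeb2, a transcription factor of terminal NK maturation, averaged 37.5 FPKM ± 2.04 in IL-15C against 46.6 ± 1.28 and fell by 0.31 ± 0.05. S1pr5, the sphingosine-1-phosphate receptor that guides NK cell exit from tissues, fell by 0.32 ± 0.06. The chemokine receptor gene Cx3cr1 fell by 0.37 ± 0.09 and the protease gene Cma1 fell by 0.32 ± 0.08. Ly6c2 rose from 207 FPKM ± 13.5 to 289 ± 30.9. Klrg1 and Itgam, surface markers of mature NK cells, had -0.03 ± 0.07 and 0.05 ± 0.06, neither past the test. Of 22 immature-stage genes, 3 rose, 2 fell and 17 did not pass; when adjusted over the list alone, 7 rose and 4 fell. Thy1, Ly6e and Cd27 rose, Ly6e by 0.54 ± 0.09. The transcription factor genes Tcf7 and Tox fell, Tcf7 from 45.7 FPKM ± 3.32 to 33.8 ± 2.29 and Tox from 10.2 ± 0.274 to 8.13 ± 0.479. Ccr2 had 0.27 ± 0.07 (limma adjusted p = 0.0547). The lists had camera adjusted p of 0.763 and 0.0968. Cx3cr1 and Cma1 lost their call under another scaling. Of the 10 called genes named here, Thy1 passed with every library left out in turn; 9 passed without IL-15C replicate 1, 7 without IL-2C replicate 3, 6 without IL-15C replicate 2 or IL-15C replicate 3, 2 without IL-2C replicate 1 and 1 without IL-2C replicate 2.

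**Figure D3:**
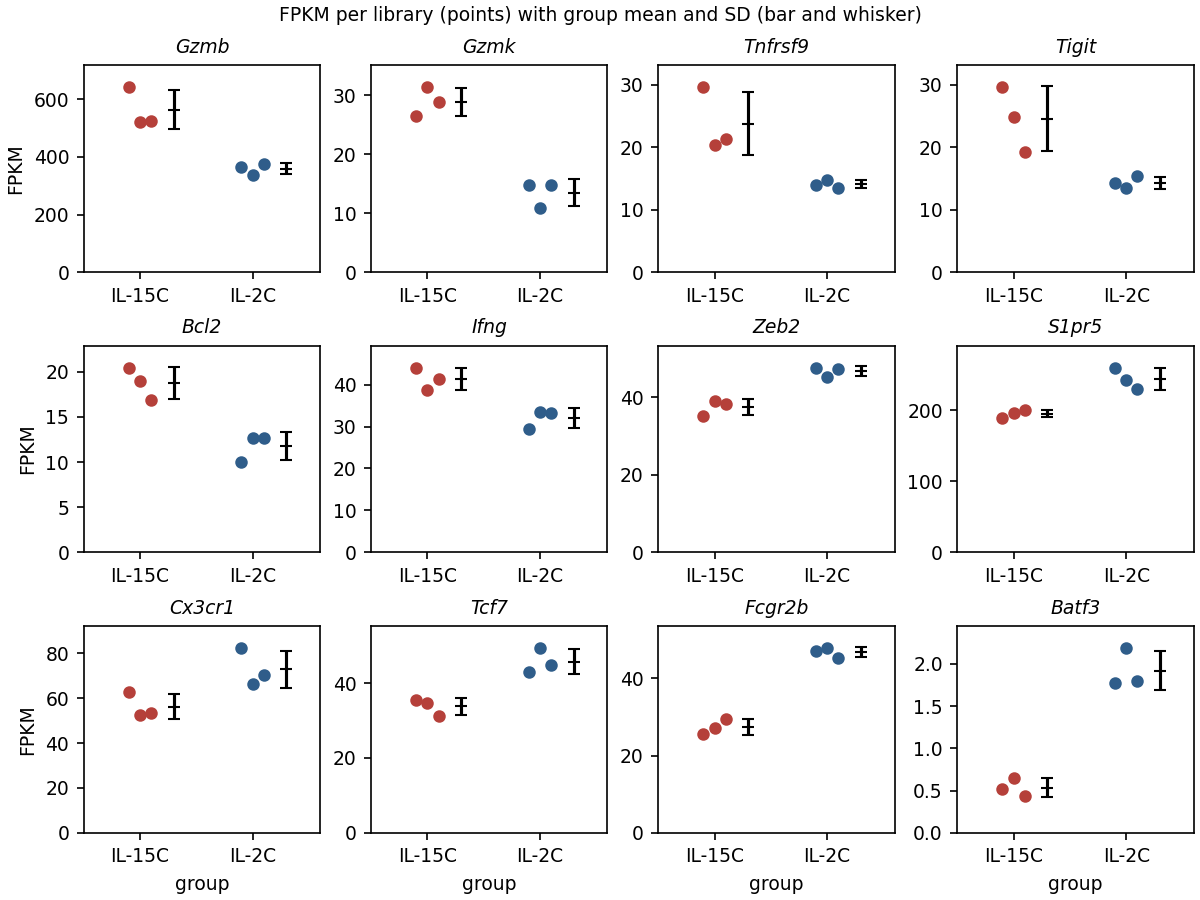
FPKM (vertical axes, from 0) of 12 genes in each library, with points for the 3 libraries per group and a bar and whisker for the group mean and SD. For Gzmb the group means are 563 in IL-15C and 360 in IL-2C, and for Fcgr2b 27.4 and 46.7; in each panel the groups do not overlap.

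Of 20 tested genes of tissue-resident group 1 innate lymphoid cells (ILC1), 0 rose, 1 fell and 19 did not pass, also when adjusted over the list alone. Rgs2, a regulator of G protein signalling, fell by 0.26 ± 0.05. The list as a whole stood above other genes (camera adjusted p = 0.0456), opposite in direction to Rgs2; the adjusted p was 0.738 with an estimated correlation, 0.739 without IL-15C replicate 1 and 0.263 without IL-2C replicate 1, and the call ended under each of the 3 other scalings. Of 21 chemokine receptor and trafficking genes, 0 rose, 3 fell and 18 did not pass; when adjusted over the list alone, 3 rose and 4 fell. The 3 were S1pr5, Cx3cr1 and Cxcr4, which binds the chemokine CXCL12 and fell from 8.84 FPKM ± 1.19 to 6.13 ± 0.783. The list had a camera adjusted p of 0.315. Rgs2 and Cx3cr1 lost their call under another scaling. Of these 4 called genes, 4 passed without IL-15C replicate 1, 2 without IL-15C replicate 3 or IL-2C replicate 3, 1 without IL-15C replicate 2 and 0 without IL-2C replicate 1 or IL-2C replicate 2 (limma).

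Cell cycle genes were split. Of 30 tested, 3 rose, 3 fell and 24 did not pass, with the same counts when adjusted over the list alone, and the camera adjusted p was 0.221. Ccne1, which encodes cyclin E1, rose by 0.40 ± 0.06, the DNA topoisomerase gene Top2a by 0.34 ± 0.05 and the thymidine kinase gene Tk1 by 0.27 ± 0.07. Stmn1, the replication helicase gene Mcm7 and the centromere histone gene Cenpa fell, Mcm7 by 0.27 ± 0.05 and Cenpa by 0.20 ± 0.05. Mki67, a marker of proliferating cells, averaged 3.47 FPKM ± 0.207 in IL-15C against 2.86 ± 0.454 (limma adjusted p = 0.137). Of 3 tested replication-dependent histone genes, 0 rose, 2 fell and 1 did not pass, also when adjusted over the list alone. Hist1h1c fell by 0.32 ± 0.08 and Hist1h4c fell by 0.46 ± 0.12. Tk1, Cenpa, Hist1h1c and Hist1h4c lost their call under another scaling. Of the 8 called genes, Stmn1 passed with every library left out in turn; 7 passed without IL-15C replicate 1, 5 without IL-2C replicate 3, 4 without IL-15C replicate 3, 3 without IL-15C replicate 2 and 1 without IL-2C replicate 1 or IL-2C replicate 2.

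Few genes of metabolism and biosynthesis passed the test. Of 48 MYC target and ribosome biogenesis genes tested by limma, 0 rose and 0 fell, also when adjusted over the list alone, while the list as a whole stood above other genes (camera adjusted p = 1.77e-06, but adjusted p = 0.738 with an estimated correlation). Its mean log2 value stood apart in IL-15C replicate 1, at 3.91, while the other IL-15C libraries had 3.66 and 3.64 and IL-2C 3.68, 3.67 and 3.60; without that library the adjusted p was 0.032. Rrp1b was nearest to a call at 0.24 ± 0.06 (adjusted p = 0.051). Of 20 glycolysis genes, 0 rose, 1 fell and 19 did not pass; when adjusted over the list alone, 1 rose and 1 fell. Bpgm, which makes 2,3-bisphosphoglycerate, fell by 0.26 ± 0.06, and Pfkp, a phosphofructokinase gene, had 0.18 ± 0.05 (adjusted p = 0.0569). The glycolysis list stood above other genes, opposite to Bpgm (camera adjusted p = 6.02e-05, adjusted p = 0.738 with an estimated correlation, and 0.00184 without IL-15C replicate 1). Of 18 genes of amino acid transport and the integrated stress response, 1 rose, 0 fell and 17 did not pass, with 3 risen when adjusted over the list alone. The serine synthesis gene Psat1 rose by 0.35 ± 0.09 (camera adjusted p of the list = 0.000687, and adjusted p = 0.738 with an estimated correlation). The mean of that list was 3.93 in IL-15C replicate 1, 3.74 and 3.72 in the other IL-15C libraries and 3.70, 3.74 and 3.63 in IL-2C, and without IL-15C replicate 1 the adjusted p was 0.00849. Of 64 oxidative phosphorylation genes, 0 rose, 1 fell and 63 did not pass, with 0 in both directions when adjusted over the list alone. The one was Ndufa6, a complex I subunit gene, which fell by 0.21 ± 0.05, and the list had a camera adjusted p of 0.0968. Of 26 lipid synthesis genes, 1 rose, 1 fell and 24 did not pass, also when adjusted over the list alone. Srebf2, the transcription factor of cholesterol synthesis, rose by 0.31 ± 0.05, and Insig1, which retains that factor in the endoplasmic reticulum, fell by 0.21 ± 0.04 (camera adjusted p of the list = 0.184). Of 25 genes of the unfolded protein response, 1 rose, 1 fell and 23 did not pass; when adjusted over the list alone, 2 rose and 1 fell. The stress sensor gene Atf6 rose by 0.21 ± 0.04 and Herpud1 fell by 0.21 ± 0.05. That list had a camera adjusted p of 0.0456, which was 0.738 with an estimated correlation, 0.827 without IL-15C replicate 1, 0.107 without IL-2C replicate 2 and 0.0897 without IL-2C replicate 3; the call also ended after median scaling and quantile normalization. Bpgm, Ndufa6 and Insig1 lost their call under another scaling. Of these 7 called genes, 7 passed without IL-15C replicate 1, 3 without IL-2C replicate 3, 2 without IL-15C replicate 3, 1 without IL-15C replicate 2 and 0 without IL-2C replicate 1 or IL-2C replicate 2.

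Of 45 interferon-stimulated genes, 4 rose, 0 fell and 41 did not pass; when adjusted over the list alone, 6 rose and 1 fell. The guanylate-binding protein genes Gbp9 and Gbp4 rose by 0.24 ± 0.04 and 0.26 ± 0.05, the antiviral gene Mx1 by 0.23 ± 0.05 and Ifi27l2a by 0.33 ± 0.08. Gbp and Ifi27 genes belong to families with close relatives, so their separate values are uncertain. The list's camera adjusted p was 5.85e-07, which was 0.738 with an estimated correlation and 5.47e-05 without IL-15C replicate 1. Its mean was 4.33 in that library, 4.17 and 4.22 in the other IL-15C libraries and 4.18, 4.14 and 4.15 in IL-2C. The groups thus overlapped. Of 24 apoptosis regulators, 2 rose, 1 fell and 21 did not pass; when adjusted over the list alone, 5 rose and 2 fell. Bcl2 was among those that rose, and Bbc3, a pro-apoptotic gene also called Puma, fell by 0.26 ± 0.05. The list's camera adjusted p was 0.0222, which was 0.738 with an estimated correlation and 0.0716 without IL-2C replicate 2; the call also ended with the B cell and class II covariate (adjusted p = 0.0556) and without a filter (adjusted p = 0.0599). Of 26 immediate early and dissociation-stress genes, 1 rose, 0 fell and 25 did not pass, also when adjusted over the list alone. The one was Egr1. This list had a camera adjusted p of 0.014, which was 0.738 with an estimated correlation, 0.0503 without IL-15C replicate 1, 0.0556 without IL-2C replicate 1 and 0.0779 without IL-2C replicate 3; the call ended after median scaling and quantile normalization. Of 75 cytosolic ribosomal protein genes, 0 rose and 0 fell by limma, also when adjusted over the list alone (camera adjusted p = 0.67). Of the 7 called genes named here, 7 passed without IL-15C replicate 1, 4 without IL-15C replicate 3, 3 without IL-15C replicate 2 or IL-2C replicate 3, 1 without IL-2C replicate 1 and 0 without IL-2C replicate 2.

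The sort markers did not differ past the test. Ncr1, which encodes NKp46, averaged 779 FPKM ± 22.0 in IL-15C against 810.5 ± 24.9, and Klrb1c, which encodes NK1.1, 527 ± 22.6 against 529 ± 24.3. Cd3e averaged 4.16 ± 0.528 against 4.52 ± 1.15. Of 7 T and NKT cell genes and 6 B and plasma cell genes tested by limma, 0 rose and 0 fell, also when adjusted over the list alone (camera adjusted p of 0.221 and 0.298). The B cell gene Cd79a averaged 1.34 FPKM ± 1.35 against 2.54 ± 1.79, and the MHC class II gene H2-Aa 3.74 ± 2.77 against 7.07 ± 4.50. The mean log2(FPKM + 1) of B cell and class II genes was 2.27, 0.80 and 1.43 in the IL-15C libraries and 2.21, 2.82 and 1.29 in IL-2C. Of 10 dendritic cell genes, 2 rose, 1 fell and 7 did not pass, also when adjusted over the list alone (camera adjusted p = 0.601). Batf3, a transcription factor of one dendritic cell lineage, averaged 0.536 FPKM ± 0.110 in IL-15C against 1.92 ± 0.232 and fell by 0.93 ± 0.09. Itgax, which encodes CD11c and is also expressed in NK cells, rose by 0.29 ± 0.05 and Ly75 by 0.23 ± 0.05. Of 6 granulocyte and mast cell genes, 1 rose, 0 fell and 5 did not pass, also when adjusted over the list alone. Retnlg rose by 0.57 ± 0.14, and the list had a camera adjusted p of 0.0356, which was 0.738 with an estimated correlation, 0.982 without IL-15C replicate 1 and 0.0509 without IL-2C replicate 1; the call ended under each of the 3 other scalings. The mean over that list was 3.49, 2.32 and 2.69 in IL-15C and 2.69, 2.67 and 2.37 in IL-2C, highest in IL-15C replicate 1, the library with the most Il10. Of 4 monocyte genes and 7 erythroid and platelet genes tested by limma, 0 rose and 0 fell, also when adjusted over the list alone, and the latter had a camera adjusted p of 0.37. Of 16 stromal and endothelial genes only Pecam1 was tested, and it rose by 0.31 ± 0.05, which as 1 gene does not speak for such cells. The 13 mitochondrially encoded genes, a measure of library quality, were not analysed here. Of these 5 called genes, Batf3 passed with every library left out in turn; 4 passed without IL-15C replicate 1, 3 without IL-15C replicate 2, 2 without IL-15C replicate 3 or IL-2C replicate 3 and 1 without IL-2C replicate 1 or IL-2C replicate 2.

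Of the 26 lists tested, 13 passed camera, all of them above other genes. With an estimated correlation 0 of the 13 passed, and by fry 0 passed. The median change, mean change and camera direction of a list differed in sign for 9 lists. Camera was upward with a median of -0.33 and a mean of -0.30 for dendritic cell genes, -0.03 and -0.02 for activating receptors, and -0.02 and -0.0095 for trafficking genes. It was upward with a negative median and a positive mean for immature-stage genes at -0.06 and 0.02, for inhibitory receptors at -0.0017 and 0.13, for T cell genes at -0.0046 and 0.03, and for cell cycle genes at -0.04 and 0.0001. It was upward with a positive median and a negative mean for oxidative phosphorylation and for lipid synthesis genes.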

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

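Among the alternatives, the tests chosen only after the result was seen are the non-overlap of deposited group intervals, the removal of GC content and length trends, the B cell and class II covariate, the retention of genes with failed estimates and the omission of genes at 0. No named gene that was called changed direction under any alternative run. Of the 69 called named genes, 56 kept their call under each of the 3 other scalings and 16 with each library left out in turn; the fewest, 8, kept it without a filter, where 16313 genes were tested. That setting called 6 genes higher and 9 lower, against 169 and 464. Median scaling gave 324 and 205 genes with 8 lists, quantile normalization 307 and 269, array weights 440 and 1667, and a 2-fold minimum 4 and 0. Removing GC content and length trends with median scaling gave 367 and 270 genes. The B cell and class II covariate gave 186 and 253, and non-overlapping deposited intervals 58 and 22, of which 38 and 12 were also called by limma. With each library left out in turn, between 14 and 175 genes were higher and between 15 and 572 lower; omission removes a residual degree of freedom, and otherwise the cause was not tested. Lists past the threshold numbered 0 with an estimated correlation and 0 by fry. The other settings kept the gene counts within 1.5 times and the list count of 13 likewise. Of the 13 lists, 7 passed under all 20 camera settings run with the preset correlation, and 0 with an estimated one. The planned overlap with Cuffdiff calls was not run, since the deposited table used here holds no calls. Changes of 0.25 on the log2 scale were recovered in 40.1% of simulated genes, which were independent of each other, unlike real genes. Many changes of that size may therefore be missed here. Genes as low as Il10 rest on 7 to 38 fragments.

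Only genes and lists without a call changed sign, and the cause was not tested. Klrg1, at -0.03, was 0.011 after median scaling, 0.031 with array weights and 0.036 with GC and length trends removed, and ran from -0.092 to 0.036 over omitted libraries. Ncr1, at -0.06, was 0.013 with GC and length trends removed. Klrb1c was 0.038 after median scaling, 0.012 rescaled to TPM, 0.022 after quantile normalization, 0.053 with GC and length trends removed and 0.014 with the B cell covariate, and ran from -0.037 to 0.034 over omitted libraries. Cd3e was 0.061 and Cd79a 0.051 with the B cell covariate, and Cd3e ran from -0.235 to 0.068 over omitted libraries. By fry the direction differed for activating receptors (adjusted p = 0.797), trafficking (0.880), cell cycle (0.955), oxidative phosphorylation (0.955), lipid synthesis (0.955), erythroid and platelet (0.955) and dendritic cell genes (0.797). The camera direction turned for dendritic cell genes after median scaling (0.890), with array weights (0.982) and with GC and length trends removed (0.878), and for cell cycle genes at a mean of at least 5 FPKM (0.475). With array weights it turned for mature-stage (0.492) and ribosomal protein genes (0.184). Over omitted libraries, adjusted p ran from 0.167 to 0.835 for activating receptors, 0.307 to 0.982 for mature-stage genes, 0.00311 to 0.982 for oxidative phosphorylation, 0.0744 to 0.916 for ribosomal proteins and 0.0285 to 0.778 for erythroid and platelet genes, with a turned camera direction in at least 1 omission of each.

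The sample titles do not say whether the replicate numbers pair the libraries. Same-numbered libraries had correlations of deviations from group means of -0.03, -0.16 and -0.02. These give no positive sign of pairing. They were not compared with those of differently numbered libraries, so weak pairing cannot be excluded. A replicate block gave 171 genes higher and 346 lower, against 169 and 464, of which 138 and 288 were also called without it. It kept the call of 61 of the 69 called named genes and ended that of the unfolded protein response list (camera adjusted p = 0.0557), and of the 13 lists the other 12 kept theirs.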

Other observations

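The tests of Il10 against counting error and B cell RNA, the removal of GC content and length trends and the B cell and class II covariate were chosen only after the data were seen.

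Some genes below the filter are given here as values. Ctla4, an inhibitory receptor gene, averaged 0.334 FPKM ± 0.124 (SD, n = 3) in IL-15C against 0.108 ± 0.051, and Havcr2, which encodes TIM-3, 0.447 ± 0.069 against 0.215 ± 0.067. The mitotic kinase gene Aurkb, whose mean over all libraries was below the filter, averaged 1.05 ± 0.046 against 0.734 ± 0.069, and the cholesterol synthesis gene Sqle 0.911 ± 0.087 against 0.584 ± 0.015. In the limma fit without a filter their adjusted p values were 0.122, 0.0863, 0.0695 and 0.0669, so none passed. The myeloid gene Mpo averaged 0.508 ± 0.2502 against 0.153 ± 0.005, with 0.771 in IL-15C replicate 1. These genes were picked after their values were seen. Some short RNA genes had erratic estimates, such as Snora70 at 1127 FPKM in IL-15C replicate 2 and 0 in the other 5 libraries.

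Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 169 genes higher and 464 lower, and the highest count of the others was 1 in each direction.

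More genes were called lower than higher, 2.75 times as many. Over omitted libraries this ratio ran from 0.704 without IL-2C replicate 1 to 3.27 without IL-15C replicate 1. Deposited group intervals that did not overlap, a different criterion, ran the other way, with 58 genes higher and 22 lower. After each library was scaled to a common median the ratio was 0.633, but that scaling centres the changes and would lower the ratio of a true shift as well, so scaling of FPKM between libraries and a true shift of most genes to lower levels in IL-15C cannot be told apart. With GC content and transcript length trends removed as well the ratio was 0.736, but that correction includes the same scaling, so a part played by GC content or length cannot be told apart either.

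Il10 was listed at 3.19 times the IL-2C mean in IL-15C, mostly through replicate 1. Counting error alone was tested without that library: replicates 2 and 3 held 29 implied fragments against 23 in the 3 IL-2C libraries, a ratio of 1.97 with an exact 95% interval from 1.10 to 3.57, which lies close to 1. RNA from B cells, which the sort would remove and which can express Il10, was tested over all 6 libraries with the B cell and class II signal as a covariate; the difference in Il10 was 0.431 FPKM with a 95% interval from -0.144 to 1.01, and 0.151 without IL-15C replicate 1. IL-2C replicate 2 had more of that signal than IL-15C replicate 1, 2.82 against 2.27, and fewer Il10 fragments, 7 against 38, but these are single libraries and their B cells can differ in Il10. With so few libraries, RNA from B cells and an effect of IL-15C on NK cells cannot be told apart, and RNA from myeloid cells, which the sort would also remove and whose signal was highest in replicate 1, was not tested and stays open too.

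Fcgr2b is strongly expressed in B cells and Batf3 in some dendritic cells, so less RNA from such cells in IL-15C, although the sort would remove both, is a candidate explanation of their lower level. With the B cell and class II signal of each library as a covariate, Fcgr2b changed by -0.76 and Batf3 by -0.91, against -0.75 and -0.93 without it, and the B cell gene Cd79a averaged 2.54 FPKM in IL-2C where Fcgr2b averaged 46.7. The smaller share kept was 98.5%, with limma adjusted p of 0.00181 and 0.00638, which argues against that source. Over the alternatives the adjusted p ran from 6.11e-05 to 0.0266 for Fcgr2b and from 0.00029 to 0.0422 for Batf3. A difference between the treatments within NK cells stays open as a hypothesis.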
